A study of Drosophila melanogaster with 16 samples.

How the data were processed

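Expression was measured on Affymetrix Drosophila arrays in control embryos and in embryos that overexpressed gcm (labelled scagcm), at stage 11, either as whole embryos or as mCD8-GFP cells purified with magnetic beads. The deposited table gives 1 intensity per probe set and array on a linear scale, with 1 decimal, from 0 to 12846.6. How the authors computed and scaled these intensities is not given in the sources used here. The 16 arrays fall into 4 groups by their titles, sorted control, sorted gcm, whole control and whole gcm, each with replicates 1 to 4. Sorted gcm 2 and sorted gcm 3 were identical in all 14010 values and were entered once, so 15 distinct arrays were compared.

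The median intensity per array ran from 31.8 to 58.4, and 28.1% to 35.8% of probe sets had an intensity below 16. The means of the arrays, trimmed at 2% and 98%, differed 2.48-fold. By a rule set before the data were examined, deposited values were to be used as they were only if these means lay within 5% of each other, so the arrays were quantile normalised together. Values were then taken as log2 of the intensity plus 16. The 44 control probe sets were left out of the tests, which left 13966, and no filter on dim probe sets was applied. The platform table gave 1 gene symbol for 12443 probe sets, several for 327 and none for 1196. Of the probe sets with 1 symbol, 12394 matched a gene of assembly release 6, which was used for names, gene positions and genomic gene length, introns included. They represent 10844 genes, 1209 of them with several probe sets. No symbol had to be updated.

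Groups were compared in R 4.3.3 with limma 3.58.1, as 1 mean per group in a fit of all arrays, with moderated variances that follow the intensity trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and probe sets with an adjusted p under 0.05 were called. The 5 comparisons were gcm against control in sorted cells, gcm against control in whole embryos, sorted cells against whole embryos in controls and in gcm embryos, and the interaction of gcm and sorting. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 18 lists and 5 comparisons, with the probe set of the highest mean for each gene. The lists were glial genes, septate junction, hemocyte, tendon cell, neuron, neuroblast and neuroectoderm, Notch pathway and E(spl) complex, mesoderm and muscle, endoderm with yolk and amnioserosa, trachea, salivary gland, germ cell and maternal, segment polarity and pair rule, EGFR and FGF signalling, cell cycle, heat shock and dissociation stress, apoptosis, and ribosomal proteins taken by symbol. No list call in any comparison held with a correlation estimated from the data. Members of a list were also counted when adjusted over the list alone.

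The comparisons, tests, lists and alternatives were fixed before the data were examined, and so was the rule for named genes. This rule names gcm, gcm2 and repo, the 12 probe sets with the largest rise and the 12 with the largest fall among calls with 1 gene symbol and no overlap between the groups compared (for the interaction without the condition on overlap), and up to 4 members per list with the smallest p. Other list members named in the text, such as loco, drpr and the genes of the heat shock and dissociation stress list, and the genes shared by both gcm comparisons outside this rule, were chosen after their values were seen. Leaving out the array labelled whole control 3 was among the fixed alternatives. Its use as a second fit throughout, its combinations with other alternatives, a count of both copies of the twice-deposited array and a quantile normalisation within sorted and within whole embryo arrays were added after the data were seen.

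Other splits of the same arrays into groups of the same sizes were counted, all 35 for a comparison of 2 groups and 100 drawn for the interaction, the latter also with the effect of gcm common to sorted cells and whole embryos removed. The alternatives fixed in advance were a pseudocount of 1 or 64, the values as deposited, median centring, the dimmest 40% of probe sets left out, no intensity trend, array weights, only the arrays of the groups compared, the replicate number as a block, and each array left out in turn. For lists, they were an estimated correlation and the mean over a gene's probe sets. Whether equal replicate numbers mark arrays that belong together was checked by correlating residuals. In whole gcm embryos without the array labelled whole control 3 the 3 pairs of the same number had correlations of 0.201 to 0.342 with whole controls, against -0.285 to 0.288 for other pairings, so the blocked count is printed beside that result. In the other comparisons at least 1 pair of the same number was negative.

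The pipeline was tested on simulated data with 15 arrays and 13966 probe sets, with 100 changed probe sets at each size. Means and spreads were taken from the real arrays other than the array labelled whole control 3, and the noise was independent between arrays. Changes were placed only in probe sets with a control level above 7. The rates below therefore do not describe the real fit of all 15 arrays, which holds that array. In the layout of the sorted comparison 57% of changes of 1 log2 unit and 95% of changes of 2 were recovered, with 7 false calls among 159. In that of the whole embryos 73% and 98% were recovered, with 13 false calls among 184. The median standard error of a gcm effect in the real data was 0.288 in sorted cells and 0.267 in whole embryos with all arrays, and 0.232 in both without the array labelled whole control 3.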

Results

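Transcript levels were measured on Affymetrix Drosophila arrays in embryos at stage 11. The arrays read either whole embryos or cells purified with anti-mCD8 magnetic beads after dissociation, from control embryos and from embryos that overexpressed gcm. The purified cells were neuroectodermal cells that carried mCD8-GFP, a membrane protein fused to a fluorescent tag. Of 16 deposited arrays, sorted gcm replicates 2 and 3 held identical values in every probe set and were counted as 1 array. That left 15 arrays, with 4 of sorted control cells, 3 of sorted gcm cells, 4 of whole control embryos and 4 of whole gcm embryos. The trimmed mean intensity ran from 67.2 to 166 across the 15 arrays. It was 94.2 ± 14.8 (SD, n = 7) in sorted arrays and 130 ± 19.0 (SD, n = 7) in whole embryo arrays other than the array labelled whole control 3, which had 83.7. The number of arrays limits the precision of every comparison. Nothing in the labels says that replicates came from separate collections of embryos, so the p-values measure only the spread between these arrays. Levels below are log2 of the normalised intensity plus 16. A level under 5 is an intensity under 16, near background, and the size of a change from or to such a level depends on the pseudocount.

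The array labelled whole control 3 stood apart from the other whole embryo arrays. Its mean correlation across probe sets was 0.690 with them and 0.931 with the sorted arrays. The other whole embryo arrays reached 0.949 to 0.968 with one another, and the sorted arrays 0.921 to 0.951. Probe sets are not independent replicates, so these correlations describe the profiles and carry no p-value. The level of gcm on this array was 13.10, against 8.07 to 8.66 on the other whole control arrays and 13.01 to 13.13 on the sorted gcm arrays. The level of repo was 10.77, against 6.14 to 6.32 and 10.67 to 11.27. The counts and most called lists are therefore given with all 15 arrays and again without this array, a fit fixed beforehand as 1 of the alternatives and chosen for this use after the data were seen.

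The overexpressed gene gcm, which encodes the transcription factor that starts glial fate, was highest in sorted gcm cells. Its level, without the array labelled whole control 3, was 8.42 ± 0.30 (SD, n = 3) in whole control embryos and 10.77 ± 0.33 (SD, n = 4) in whole gcm embryos. In sorted cells it was 11.66 ± 0.36 (SD, n = 4) in controls and 13.09 ± 0.06 (SD, n = 3) with gcm. The glial homeobox gene repo, a known target of gcm, stood at 6.22 ± 0.10 (SD, n = 3) and 8.13 ± 0.32 (SD, n = 4) in whole control and whole gcm embryos. It reached 8.53 ± 0.41 (SD, n = 4) in sorted control cells and 10.98 ± 0.31 (SD, n = 3) in sorted gcm cells. The related gene gcm2 was at 5.93 ± 0.03 (SD, n = 3) and 5.61 ± 0.33 (SD, n = 4) in whole control and whole gcm embryos. In sorted cells gcm2 was at 6.75 ± 0.10 (SD, n = 4) in controls and 6.78 ± 0.19 (SD, n = 3) with gcm. On sorted gcm arrays gcm lay near the highest normalised value, 13.41, which limits its change and its spread there. Each gene was read by a single probe set. In assembly release 6, gcm lies on chromosome 2L from 9579498 to 9581745, gcm2 on 2L from 9608562 to 9612706, and repo on 3R from 18236192 to 18239602. Whether the gcm probe set reads the introduced transcript, the resident one or both is not given in the sources used here.

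**Figure D1:**
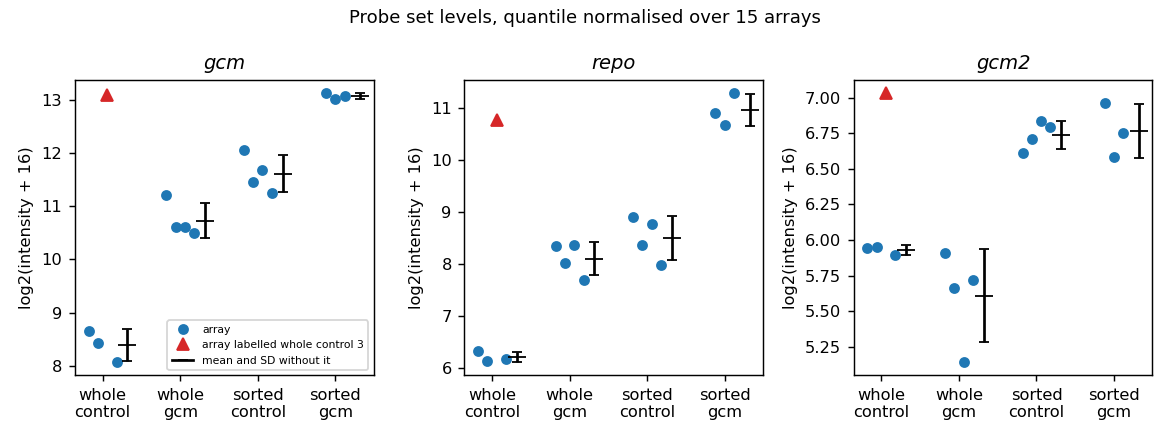
Levels of gcm, repo and gcm2 on each of the 15 arrays by group, as log2 of the quantile normalised intensity plus 16. Circles are arrays, the triangle is the array labelled whole control 3, with gcm at 13.10 and repo at 10.77, and bars give mean and SD without it.

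The first comparison asked which transcripts differ in purified cells when gcm is overexpressed. Ect3, which encodes a beta-galactosidase, rose most, from 8.19 ± 0.43 (SD, n = 4) in sorted control cells to 12.27 ± 0.11 (SD, n = 3) in sorted gcm cells, 17.0-fold (adjusted p = 0.00879, limma). Nagk, an N-acetylglucosamine kinase, rose from 8.43 ± 0.26 (SD, n = 4) to 11.17 ± 0.14 (SD, n = 3). Sardh, a sarcosine dehydrogenase, rose by 2.21 on the log2 scale, MFS16, a transporter of the major facilitator superfamily, by 1.90 and NimC4, a receptor for the uptake of dying cells, by 1.34. Ank2, the neuronal ankyrin, fell from 6.52 ± 0.12 (SD, n = 4) to 4.88 ± 0.03 (SD, n = 3), and the chitin-binding protein gene obst-A fell by 1.66 and grnd, which encodes a receptor for the tumour necrosis factor Eiger, by 1.42. With all 15 arrays, 17 of 13966 probe sets were called, 12 higher and 5 lower in sorted gcm cells. The gene gcm itself was higher by 1.46 (SE 0.84, adjusted p = 0.982) and repo by 2.45 (SE 0.81, adjusted p = 0.518), and neither was called.

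The same sorted arrays gave, without the array labelled whole control 3, 108 calls, 71 higher and 37 lower, with all 17 earlier calls among them. Markers of glia were among those that rose: repo by 2.46 (SE 0.23, adjusted p = 1.86e-05), moody, a receptor of the glia that form the blood-brain barrier, by 1.88 (SE 0.24), and the FGF receptor htl by 0.97 (SE 0.15). The gene gcm rose by 1.43 (SE 0.22, adjusted p = 0.00321), limited by that highest value, and by 1.92 with the values as deposited and 1.87 with median centring. The related gene gcm2 differed by 0.03 (SE 0.21, adjusted p = 0.986). Ect3 rose by 4.11, CG12910 by 3.11 and Nagk by 2.75. Among the genes that fell were nerfin-1, a zinc finger factor of newborn neurons, by 1.92 from 11.62 ± 0.24 (SD, n = 4) to 9.71 ± 0.46 (SD, n = 3), HGTX, a homeobox gene of motor neurons, by 1.96, and fne, an RNA-binding protein of the Elav family, by 1.17. The POU gene nub fell by 0.98 and the homeobox gene al by 1.21. The genes named here for the size of their change were chosen to have no overlap between the groups, so this is no support for them. Such separation held for 9.09% of all probe sets, where chance gives 5.71%. The left-out array belongs to neither group compared, and it acts through the normalisation and the spread that all groups share. The count of 108 became 56 without the twice-deposited sorted gcm array and 183 without sorted control 4, while that of 17 became 11 without that sorted gcm array, 11 without sorted control 2 and 8 without sorted control 3. With the replicate number as a block limma called 0 from all arrays (694 and 817 probe sets with an unadjusted p under 0.05, by the number given to the twice-deposited array). It called 55 and 58 from 14. From 14 arrays 49 were higher and 9 lower with the values as deposited, and 43 and 11 with median centring. A fit of only the sorted arrays called 38.

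Among the lists of genes, the trachea list was lower in sorted gcm cells, with a median change of -0.71 (camera adjusted p = 7.30e-07 in the limma fit, and adjusted p = 0.628 with an estimated correlation). All members measured, 13 in number, had a negative change, and 0 were called over all probe sets by limma, where 776 probe sets had an unadjusted p under 0.05, and 1 adjusted over the list alone. The median was -0.72 without the array labelled whole control 3 (adjusted p = 6.44e-10, and 0.512 with an estimated correlation), and 2 members fell over all probe sets and 9 adjusted over the list alone. Those 2 were kni, a transcription factor of segmentation and tracheal branching, by 1.05, and sano by 0.85. The segment polarity and pair rule list was lower with a median of -0.33 in both fits (adjusted p = 0.00642 and 0.00473, and 0.628 and 0.534 with an estimated correlation). Of its 18 members 0 were called over all probe sets by limma in both fits (776 and 1482 probe sets with an unadjusted p under 0.05), and 4 fell adjusted over the list alone without the array labelled whole control 3, ftz and slp2 among them with changes of -0.89 and -0.79. The neuroblast and neuroectoderm list was lower with a median of -0.20 (adjusted p = 0.0115, and 0.628 with an estimated correlation). It was also lower without the array labelled whole control 3 (adjusted p = 0.0116, and 0.713 with an estimated correlation), and nub fell both over all probe sets and adjusted over the list alone among its 33 members. The neuroblast call ended without sorted gcm 4 (adjusted p = 0.0672 from all arrays and 0.0846 from 14) and the segment polarity call without the twice-deposited array (0.0663 and 0.0748). These lists kept a negative median with the values as deposited and with median centring. The log2 ratio of 3' to 5' signal for actin was 1.63 ± 0.06 (SD, n = 4) in sorted control and 1.89 ± 0.26 (SD, n = 3) in sorted gcm arrays. For eIF-4a it was 1.04 ± 0.16 and 0.98 ± 0.08. Without the array labelled whole control 3, the gcm effect in sorted cells had a Spearman rho of -0.115 with gene length. Whether these measures bear on the lists was not tested.

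The glial list was not called in sorted cells, and its members moved in both directions. Its median was -0.08 and its mean 0.11 across 20 members, with an adjusted p of 0.877 with all arrays and 0.495 without the array labelled whole control 3. In the second fit 3 members rose over all probe sets (repo, moody and htl), and adjusted over the list alone 5 rose and 3 fell. The members that rose adjusted over the list alone included loco, a regulator of G protein signalling, with a change of 0.65 and the engulfment receptor drpr with 0.58, and those that fell were the gap junction genes Inx2 (-0.88) and ogre (-0.66) and the sodium pump subunit nrv2 (-0.56). Of the 26 neuron genes, 2 fell over all probe sets without the array labelled whole control 3 (nerfin-1 and fne), and 1 rose and 4 fell adjusted over the list alone. The ribosomal protein list was called only without that array, with a median of 0.24 (adjusted p = 7.22e-04, and 0.727 with an estimated correlation), and 0 of its 37 members were called by limma over all probe sets, where 1482 had an unadjusted p under 0.05, or adjusted over the list alone. That call ended when the twice-deposited sorted gcm array was also left out (adjusted p = 0.977).

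The second comparison asked what gcm does to the profile of whole embryos, without purification. Some transcripts known as maternal were higher in whole gcm embryos: twe, a phosphatase of meiosis, rose from 5.93 ± 0.76 (SD, n = 4) to 8.30 ± 0.65 (SD, n = 4), 5.18-fold (adjusted p = 0.0443, limma), and the receptor gene tor, which patterns the embryo's termini, rose by 2.12. The lectin gene galectin rose by 1.42, the iron regulatory gene Irp-1B by 1.37 and the formin gene DAAM by 1.12. The homeobox gene al fell by 1.67 (SE 0.28), from 6.64 ± 0.63 (SD, n = 4) to 4.96 ± 0.20 (SD, n = 4). With all 15 arrays, 8 probe sets were called, 7 higher and 1 lower, and the other 2 genes that rose were CG3618 and CG11035. The count was 3 with the values as deposited, 68 with median centring and 1144 with array weights. A limma fit of only the whole embryo arrays called 0 (1092 probe sets with an unadjusted p under 0.05). Neither gcm, higher by 1.17 (SE 0.78, adjusted p = 0.604), nor repo, higher by 0.75 (SE 0.75, adjusted p = 0.729), was called.

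In whole embryos 62 probe sets were called without the array labelled whole control 3, 51 higher and 11 lower, with the 8 earlier calls among them. Of these, gcm rose by 2.35 (SE 0.22, adjusted p = 6.40e-05) and repo by 1.91 (SE 0.23, adjusted p = 8.88e-04). CG13101 rose by 2.66, CG12910 by 2.09 and Nagk by 1.70. Among maternal transcripts twe rose by 2.16, tor by 1.76 and bcd, which encodes the anterior determinant, by 1.62, from 5.86 ± 0.40 (SD, n = 3) to 7.48 ± 0.35 (SD, n = 4). The genes al, nerfin-1 and fd96Cb, a forkhead gene, fell by 1.38, 1.32 and 1.27. The related gene gcm2 differed by -0.32 (adjusted p = 0.654). Separation without overlap held for 12.3% of probe sets, where chance gives 5.71%, and with all arrays for 6.03%, where chance gives 2.86%. In the fit without that array whole embryo arrays of the same number resembled each other, and with the number as a block 95 or 31 probe sets were called, depending on the number given to the twice-deposited array, while from all arrays limma then called 0 (1454 and 1392 with an unadjusted p under 0.05). The 62 calls became 10 without whole control 1, 199 without whole control 2, 12 without whole control 4, 462 without whole gcm 1, and 16, 20 and 17 without whole gcm 2, 3 and 4. They became 24, 28 and 39 without sorted control 1, 2 and 3, and 28 and 31 without sorted gcm 1 and 4, arrays that are in neither group. With all arrays, 104 were called without whole control 2, 185 without whole gcm 1, 14 without sorted control 4, and 1 without sorted control 2, sorted control 3 or whole gcm 2. It was 0 by limma without sorted control 1, any sorted gcm array, whole control 1 or 4, or whole gcm 3 or 4, where 1055 to 2183 probe sets had an unadjusted p under 0.05. Without the array labelled whole control 3, the share of calls that were higher was 82.3%, and 51.9% with the values as deposited, which moved the median change of all probe sets to -0.19 from -0.02, while no called probe set changed sign. The values as deposited gave 27 calls, 14 higher and 13 lower, and median centring gave 100, 92 higher and 8 lower. A fit of only the whole embryo arrays called 13.

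Lists of patterning and neural genes were lower in whole gcm embryos. The Notch pathway and E(spl) complex list had a median of -0.57 with all arrays (adjusted p = 0.00177, and 0.628 with an estimated correlation) and -0.41 without the array labelled whole control 3 (adjusted p = 7.22e-04, and 0.596 with an estimated correlation). The trachea list had medians of -0.71 (adjusted p = 1.33e-04, and 0.628 with an estimated correlation) and -0.28 (adjusted p = 7.66e-04, and 0.534 with an estimated correlation). The segment polarity and pair rule list had medians of -0.36 (adjusted p = 0.00659, and 0.628 with an estimated correlation) and -0.34 (adjusted p = 7.22e-04, and 0.512 with an estimated correlation). The neuroblast and neuroectoderm list had medians of -0.32 (adjusted p = 0.0254, and 0.628 with an estimated correlation) and -0.24 (adjusted p = 0.0213, and 0.727 with an estimated correlation), and without that array its call ended with the number as a block. It also ended without whole control 1 or 2 or whole gcm 3 or 4 (adjusted p from 0.0663 to 0.106, and from 0.0675 to 0.186 when the array labelled whole control 3 was left out too). Over all probe sets limma called 0 members of these 4 lists in both fits, where 1560 and 1622 probe sets had an unadjusted p under 0.05. Adjusted over the list alone and without that array, 3 trachea genes, 3 neuroblast genes, 1 segment polarity gene and 0 Notch genes fell. All 4 lists kept a negative median with the values as deposited and with median centring.

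A further set of lists was called in whole embryos with the array labelled whole control 3 and not without it. These were the neuron list with a median of -0.27 (adjusted p = 0.00960, and 0.628 with an estimated correlation), the EGFR and FGF signalling list with -0.34 (adjusted p = 0.0405, and 0.666 with an estimated correlation) and the ribosomal proteins with 0.82 (adjusted p = 7.21e-05, and 0.666 with an estimated correlation). Without it their medians were -0.20, -0.12 and 0.02 (adjusted p = 0.0635, 0.663 and 0.741), and the ribosomal median turned to -0.13 with the values as deposited. The EGFR call also ended without whole control 2 (adjusted p = 0.0561), whole gcm 3 (0.111) or whole gcm 4 (0.0709). Over all probe sets 0 members of these lists were called by limma with all arrays, where 1560 probe sets had an unadjusted p under 0.05, and adjusted over the list alone 2 neuron genes and 1 EGFR gene fell and 0 ribosomal genes changed. The glial list was not called in whole embryos with all arrays (median -0.31, adjusted p = 0.0736) or without that array (median -0.22, adjusted p = 0.864), where repo rose over all probe sets and, adjusted over the list alone, repo rose and nrv2 fell. The germ cell and maternal list was not called either (median 0.09 in both fits, adjusted p = 0.0969 and 0.169). From 14 arrays it had 2 members that rose over all probe sets, bcd and twe, and 3 adjusted over the list alone.

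The effects of gcm in sorted cells and in whole embryos were then set against each other. With all 15 arrays, 0 probe sets were called in both by limma, where 776 and 1560 had an unadjusted p under 0.05. Without the array labelled whole control 3, 14 probe sets were called in both and all moved in the same direction, 11 higher, where 0.259 would be shared by chance, and 3 lower, where 0.0291 would be. They covered 13 named genes: gcm, repo, Ect3, Nagk, CG12910, CG9541, CG15822, CG32037, Jhbp1 and dnd, which rose, and al, meru and nerfin-1, which fell. The chance counts of 0.259 and 0.0291 treat the 2 sets of calls as independent, although both use 1 shared estimate of spread per probe set. Of the 108 probe sets called in sorted cells 89 had the same sign in whole embryos, and of the 62 called in whole embryos 42 had the same sign in sorted cells. Across all probe sets the fold changes had a Pearson r of 0.106 and a Spearman rho of 0.0613 without that array, and 0.241 and 0.230 with it. The count of shared probe sets was 6 when whole control 1 was also left out, 8 without whole control 4 or whole gcm 3, and 9 without the twice-deposited sorted gcm array, whole gcm 2 or whole gcm 4. It also fell below 14 with the replicate number as a block and in fits of only the groups compared.

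**Figure D2:**
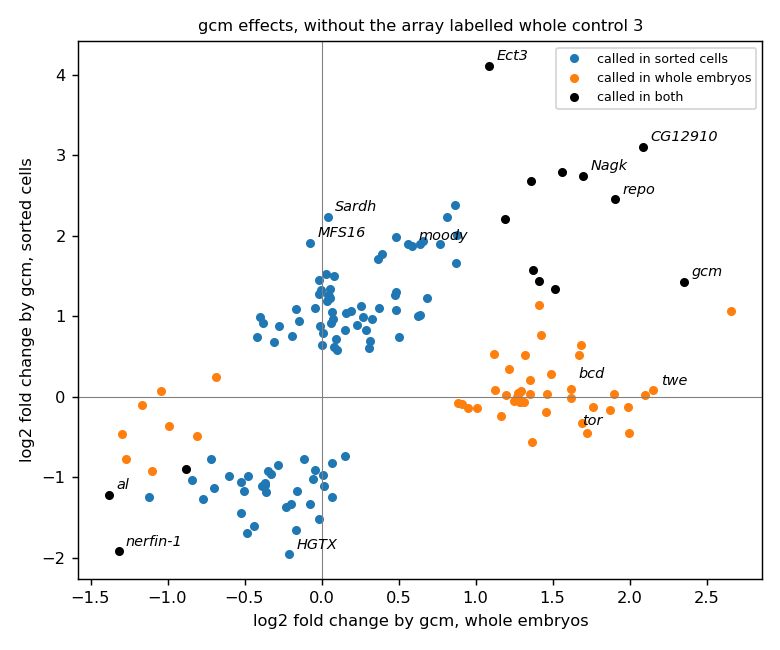
Log2 fold change by gcm in whole embryos (horizontal axis) and in sorted cells (vertical axis) for each probe set called in either, without the array labelled whole control 3. The 14 probe sets called in both lie in the upper right and lower left quadrants.

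The interaction tested whether the measured effect of gcm differed between sorted cells and whole embryos. The sorted cells are a part of the embryo, so an effect confined to them would read smaller in whole embryos. The interaction cannot tell this from a different action of gcm. With all arrays only MFS16 was called, with an effect larger in sorted cells by 1.93 (SE 0.26, adjusted p = 0.0312). Without the array labelled whole control 3, Ect3 (3.02, adjusted p = 0.00111), Sardh (2.19, adjusted p = 0.0348), MFS16 (1.99, adjusted p = 0.00332) and CG3841 (1.50, adjusted p = 0.0348) were called. MFS16 went from 6.01 ± 0.31 (SD, n = 4) to 7.93 ± 0.02 (SD, n = 3) in sorted cells and lay at 8.28 ± 0.19 (SD, n = 3) and 8.21 ± 0.12 (SD, n = 4) in whole control and whole gcm embryos. Sardh was at 4.88 ± 0.01 (SD, n = 3) and 4.93 ± 0.09 (SD, n = 4) in whole embryos and at 4.87 ± 0.27 (SD, n = 4) and 7.10 ± 0.53 (SD, n = 3) in sorted cells. The effects on gcm and repo were not shown to differ, with differences of -0.92 (adjusted p = 0.272) and 0.55 (adjusted p = 0.591). For gcm, near the highest normalised value in sorted gcm cells, the difference was -0.31 with the values as deposited and -0.62 with median centring. The Notch list was higher in the difference by a median of 0.43 with all arrays (adjusted p = 0.0139, and 0.628 with an estimated correlation) and 0.27 without that array (adjusted p = 0.0275, and 0.727 with an estimated correlation). The cell cycle list was called only with all arrays (-0.25, adjusted p = 0.0206, and 0.723 with an estimated correlation) and had a median of 0.14 without that array. The ribosomal list was called only without it (0.24, adjusted p = 0.0325, and 0.842 with an estimated correlation) and had -0.54 with it (adjusted p = 0.0593). Over all probe sets, and adjusted over the list alone, 0 members of these lists were called by limma, where 877 and 1468 probe sets had an unadjusted p under 0.05. From all arrays the Notch call ended without the twice-deposited array (adjusted p = 0.171), and the cell cycle call without sorted control 1, sorted gcm 4 or whole gcm 1 (0.0534 to 0.0606). From 14 arrays the Notch call ended without sorted control 4, sorted gcm 1, the twice-deposited array, whole control 1 or 2, or whole gcm 3 or 4 (0.0522 to 0.355). The ribosomal call ended without sorted control 1, 3 or 4, the twice-deposited array, whole control 4 or whole gcm 1 (0.0525 to 0.749). With the values as deposited limma called 0 probe sets with all arrays, where 921 had an unadjusted p under 0.05, and the call of MFS16 ended without any 1 of 11 arrays: sorted control 1, 2 or 4, whole control 1 or 4, or whole gcm 2, 3 or 4 (0 calls by limma, 647 to 1046 probe sets with an unadjusted p under 0.05), or any sorted gcm array (2 other calls). Without whole control 2 there were 3 calls and without whole gcm 1 there were 4. With the replicate number as a block limma called 0 in both fits (758 and 764 with an unadjusted p under 0.05 from all arrays, 1746 and 1761 from 14), so the 4 calls ended too. The 4 calls became 64 without whole gcm 1, 15 without whole control 2, 14 without sorted control 4, 7 without the twice-deposited sorted gcm array, and 2 without sorted control 1 or 3, whole control 1 or 4, or whole gcm 2, 3 or 4.

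The remaining comparisons asked how purified cells differ from whole embryos of the same genotype. In controls, some genes known from neurons were higher in the sorted cells: nerfin-1 rose from 8.70 ± 0.94 (SD, n = 4) to 11.58 ± 0.23 (SD, n = 4), 7.32-fold (adjusted p = 0.00127, limma), fne by 2.85, the neuronal RNA-binding gene elav by 2.44 and the zinc finger gene zfh1 by 3.07. The patterning genes tsh and stan rose by 3.51 and 3.59. Ribosomal protein genes were lower: RpS21 fell from 10.93 ± 2.63 (SD, n = 4) to 6.70 ± 0.18 (SD, n = 4) (adjusted p = 0.00665), RpS20 fell by 3.91, and COX8, a gene for a subunit of cytochrome c oxidase, fell by 4.03. With all 15 arrays 3647 probe sets were called in controls, 1786 higher and 1861 lower, and without the array labelled whole control 3 the count was 6478, with 3483 higher and 2995 lower. Of the 3647, 3628 were called again. With the values as deposited 701 were higher and 2772 lower, and 1776 and 4304 without that array. Median centring gave 58.3% and 61.4% higher. Of the 6478 called, 249 changed sign with the values as deposited and 29 with median centring, and relative to the median change of all probe sets 75 did with either. Without that array nerfin-1 rose by 3.33, fne by 3.45 and sna, a zinc finger gene of neuroblasts, by 3.53, while RpS21 fell by 5.58 and RpL29 from 12.37 ± 0.15 (SD, n = 3) to 4.24 ± 0.07 (SD, n = 4), near background. The genes gcm and repo rose by 3.24 (adjusted p = 8.22e-09, and by 2.20 with the values as deposited) and 2.30 (adjusted p = 4.33e-07), though neither was called with all arrays (adjusted p = 0.0633 and 0.274). The 3647 calls became 1833, 1923 and 1636 without whole control 1, 2 and 4, and 0 in a limma fit of only the arrays of sorted and whole controls, where 4295 probe sets had an unadjusted p under 0.05.

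In gcm embryos, 5152 probe sets differed between sorted cells and whole embryos, 2724 higher and 2428 lower, and 6367 without the array labelled whole control 3, which is in neither group. The gene repo was higher in sorted gcm cells by 2.84 (adjusted p = 0.0125) and by 2.86 without that array, gcm by 2.34 (adjusted p = 0.0389, and 0.0614 with the values as deposited) and 2.33, and gcm2 by 1.15 and 1.17. RpL29 and bcd were lower in both fits and lay near background in sorted gcm cells, at 4.33 and 4.60 with all arrays, against 12.34 and 7.46 in whole gcm embryos. With the values as deposited 45.4% and 45.6% of calls were higher, where quantile normalisation gave 52.9% and 54.1%. Without that array 5065 probe sets were called in the same direction in both genotypes, 2707 higher against 859 by chance and 2358 lower against 627, and 8 in opposite directions. The fold changes had a Pearson r of 0.924 and a Spearman rho of 0.880 across probe sets. These comparisons share no arrays, but they share 1 estimate of spread per probe set, which the chance counts leave out. Separation without overlap held for 47.1% of probe sets in controls without that array and 50.7% in gcm embryos, where chance gives 5.71%, and in controls for 11.3% with all arrays, where chance gives 2.86%.

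Of 37 ribosomal protein genes, 31 fell on sorting in controls over all probe sets and adjusted over the list alone (median -2.59, adjusted p = 1.98e-12, and 0.628 with an estimated correlation). Of these genes 32 fell and RpL22-like rose without the array labelled whole control 3 (median -3.46, adjusted p = 4.06e-18, and 0.512 with an estimated correlation). In gcm embryos 30 fell with all arrays, and 31 adjusted over the list alone, and 1 rose (median -3.32, adjusted p = 8.24e-11, and 0.628 with an estimated correlation). Left out, that array gave 31 that fell and 1 that rose by both counts (median -3.35, adjusted p = 2.11e-17, and 0.512 with an estimated correlation). The cell cycle list was lower in controls, with a median of -0.36 with all arrays (adjusted p = 0.0378, and 0.739 with an estimated correlation) and -0.60 without that array (adjusted p = 0.00167, and 0.512 with an estimated correlation). In the second fit 10 of its 18 genes fell over all probe sets and adjusted over the list alone, among them aurB by 2.81 and PCNA by 2.15, and E2f1 rose by 1.92. In gcm embryos its median was -0.87 (adjusted p = 0.00428, and 0.666 with an estimated correlation), with 8 genes that fell over all probe sets and 11 adjusted over the list alone. From 14 arrays it was also -0.87 (adjusted p = 8.06e-04, and 0.512 with an estimated correlation), with 12 that fell by both counts. With all arrays the cell cycle call in controls ended without sorted control 2 or 4 or whole control 1 or 2 (adjusted p from 0.0535 to 0.104). Both lists kept their direction with the values as deposited and with median centring.

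Several lists were higher in sorted cells of control embryos. The trachea list had a median of 1.16 in controls (adjusted p = 0.00132, and 0.628 with an estimated correlation), with 8 of 13 genes that rose over all probe sets and 9 adjusted over the list alone. The median was 1.55 without the array labelled whole control 3 (adjusted p = 8.06e-04, and 0.534 with an estimated correlation), and kni rose by 3.13 and vvl by 2.66. The EGFR and FGF signalling list had 1.03 (adjusted p = 0.0186, and 0.628 with an estimated correlation) and 1.21 (adjusted p = 0.0116, and 0.534 with an estimated correlation). In it 6 of 13 genes rose over all probe sets with all arrays and 7 adjusted over the list alone, and without that array 8 rose by both counts, sty by 2.48 and htl by 1.86 among them. The tendon cell list had 0.83 (adjusted p = 0.0486, and 0.628 with an estimated correlation) and 1.18 (adjusted p = 0.0325, and 0.596 with an estimated correlation). Of its 6 genes 3 rose over all probe sets with all arrays and 5 adjusted over the list alone, and 4 rose by both counts without that array. Only without that array, the glial list was called in controls with a median of 0.90 (adjusted p = 0.0406, and 0.618 with an estimated correlation), with 12 of 20 genes that rose and 2 that fell by both counts. The neuron list was called there too with 0.26 (adjusted p = 0.0466, and 0.512 with an estimated correlation), with 10 of 26 genes that rose and 1 that fell by both counts. The tendon call ended without sorted control 3, sorted gcm 1 or 4, whole control 2 or 4, or whole gcm 3 or 4 (adjusted p from 0.0525 to 0.0841). From 14 arrays it ended without sorted control 3 (0.0540). The glial call ended without sorted control 2 or 3 or whole control 2 (0.0540 to 0.0728). The neuron call ended without sorted control 3 or 4, the twice-deposited array, sorted gcm 4, whole control 2, or whole gcm 2, 3 or 4 (0.0514 to 0.0695). The Notch list was not called in controls (median 0.79, adjusted p = 0.241), and with the values as deposited its median turned to -0.12, that of the neuroblast list to -0.40 and that of the segment polarity list to -0.20.

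In gcm embryos with all arrays, the called lists that were higher in sorted cells were trachea (1.30, adjusted p = 0.0123, and 0.628 with an estimated correlation), EGFR and FGF signalling (0.92, adjusted p = 0.00428, and 0.628 with an estimated correlation), Notch (1.17, adjusted p = 0.0440, and 0.666 with an estimated correlation) and neuron (0.29, adjusted p = 0.0230, and 0.628 with an estimated correlation). Over all probe sets 9 trachea, 8 EGFR, 9 Notch and 9 neuron genes rose, and adjusted over the list alone 10, 10, 10 and 9 did. Without the array labelled whole control 3 the glial list (0.72, adjusted p = 0.0406, and 0.618 with an estimated correlation) and the tendon cell list (1.13, adjusted p = 0.0406, and 0.596 with an estimated correlation) were called as well. The others were trachea (1.31, adjusted p = 0.00356, and 0.534 with an estimated correlation), EGFR (0.93, adjusted p = 0.00326, and 0.512 with an estimated correlation), Notch (1.18, adjusted p = 0.0462, and 0.776 with an estimated correlation) and neuron (0.29, adjusted p = 0.0278, and 0.512 with an estimated correlation). From all arrays the Notch call ended without sorted control 4, sorted gcm 1, the twice-deposited array, or whole gcm 3 or 4 (adjusted p from 0.0501 to 0.116). From 14 arrays the glial call ended without sorted control 2, 3 or 4, sorted gcm 4 or whole gcm 4 (0.0505 to 0.0581), the tendon call without sorted control 3 or 4, sorted gcm 1 or whole gcm 4 (0.0505 to 0.0540). The Notch call ended without any 1 of 9 arrays, all but sorted control 1, sorted gcm 1 and 4, and whole gcm 1 and 2 (0.0505 to 0.135). The direction of the called lists held with the values as deposited and with median centring. These scalings moved the median change of all probe sets in controls, without that array, to -0.16 and 0.27 from 0.07, and the median of the glial list to 0.22 and 0.65 and that of the neuron list to 0.04 and 0.46. Across 10799 genes the change on sorting had a Spearman rho of 0.355 with gene length in controls and 0.319 in gcm embryos. After a trend on gene length was removed, the median in controls was -0.22 for the neuron list, 0.57 for the glial list, 0.42 for EGFR and FGF signalling and 0.63 for tendon cells, all inside the range of random lists of the same size. The trachea list had 0.95, the cell cycle list -0.64 and the ribosomal proteins -3.03, all outside it.

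Control probe sets and RNA measures moved with sorting as well. The probe set for the 3' part of 18S ribosomal RNA stood at 12.95 ± 0.20 (SD, n = 7) in sorted arrays and 6.21 ± 1.54 (SD, n = 7) in whole embryo arrays other than the array labelled whole control 3, which had 13.05, as log2 of the deposited intensity plus 16. The log2 ratio of 3' to 5' signal for actin was 1.74 ± 0.21 (SD, n = 7) in sorted arrays and 0.88 ± 0.26 (SD, n = 7) in those whole embryo arrays, and 1.85 on the array labelled whole control 3. For eIF-4a the ratio was 1.01 ± 0.12 (SD, n = 7) and 1.10 ± 0.15 (SD, n = 7). These differences run with every gene group that changed on sorting, and the array labelled whole control 3 lies with the sorted arrays in the first 2 measures.

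**Figure D3:**
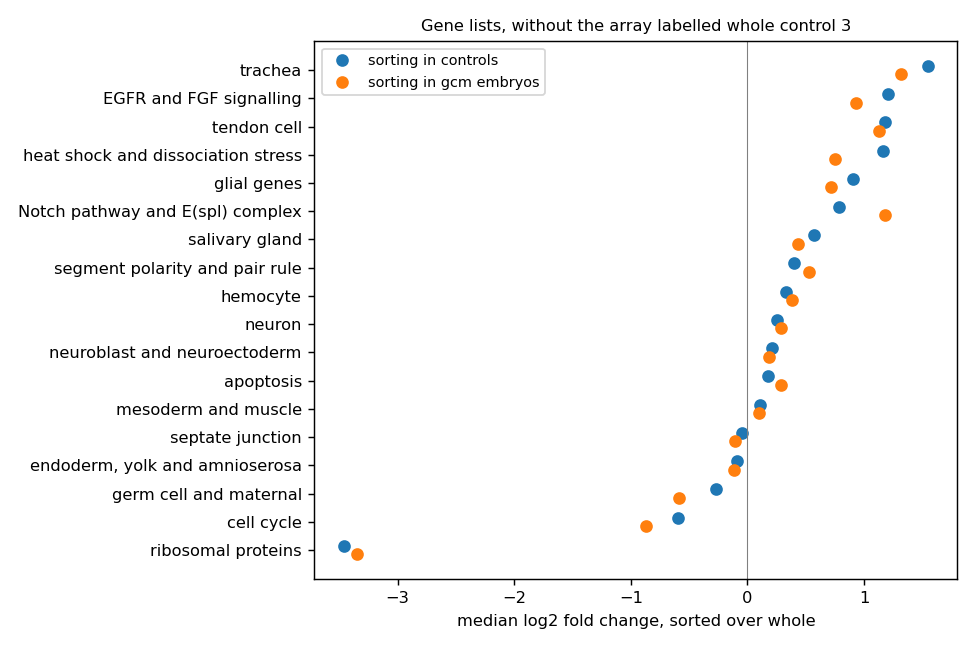
Median log2 fold change of sorted cells over whole embryos for each of the 18 lists, in controls and in gcm embryos, without the array labelled whole control 3. The ribosomal proteins lie lowest, at -3.46 in controls, and with the values as deposited the medians of the Notch, neuroblast, segment polarity, hemocyte, mesoderm, salivary gland and apoptosis lists in controls and of the mesoderm list in gcm embryos turned negative, while with median centring that of the endoderm list in controls turned positive.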

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

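Chosen after the result was seen were all tests of where the array labelled whole control 3 lies, those of short genes and of ribosomal protein genes, the maternal transcript tests with the genes named from them, the counts over splits that part pairs and those with the shared effect of gcm removed. The scaling test, the length trend on the neuron list and the counts over all splits of the 15 arrays were fixed beforehand, and the counts over all splits without that array were added after the data, though before those counts, were seen.

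The array labelled whole control 3 lay far from the other 3 whole control arrays in 5 of the 6 single values tested in that group (18 over 3 groups): gcm 13.10, gcm2 7.03, repo 10.77, a median ribosomal protein level of 7.95 and a mean correlation with the rest of its group of 0.696. Among 192 named probe sets, 54 had 1 whole control array far from the other 3, and in 49 of them it was this one, where chance gives about 1 in 20 groups, though sets named for their change on sorting are not a random draw. On the axis from whole control (0) to sorted control (1) it lay at 0.997, within the 0.848 to 1.03 of the sorted arrays and away from the -0.110 to 0.0774 of the other whole embryo arrays, and in probe sets far lower in sorted cells it differed from sorted arrays by a median of 0.0259 (sorted arrays -0.228 to 0.480, other whole embryo arrays 5.10 to 5.48), which argues against whole embryo RNA mixed with RNA of sorted cells. Its position from sorted control (0) to sorted gcm (1), 0.702, argues against a sorted control array (0.0718 to 0.378), so that a sorted array under a whole embryo label is a candidate explanation. Its gcm (13.10) and repo (10.77) levels lay within those of the sorted gcm arrays (13.01 to 13.13 and 10.67 to 11.27). Both lay above those of the sorted control arrays (11.25 to 12.07 and 7.98 to 8.89), which goes with a sorted gcm array. Its gcm level lay near the highest normalised value, though. As deposited, without scaling, its gcm and repo intensities (6662.4 and 1112.4) lay above every sorted control array and below every sorted gcm array. Its mean correlation was 0.933 with sorted control and 0.928 with sorted gcm arrays. All sorted gcm arrays correlated more with sorted gcm, but so did sorted control 2 and 4. The position of 0.702 lies just under the 0.710 to 0.942 of only 3 such arrays, so this was not settled, and no biological explanation was tested.

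The change on sorting followed gene length, with a Spearman rho of 0.355 in controls and 0.319 in gcm embryos, and ribosomal protein genes, which are short, were far lower in sorted cells. Array scaling alone is argued against, since without quantile normalisation the ribosomal median was -3.82 and -4.24, and so is a trend on gene length over all genes as the whole cause, since with that trend removed the median was -3.03, outside the -0.243 to 0.473 of random lists. The higher neuron list is a different case: after a trend on length was removed its median was -0.215, within the -0.333 to 0.520 of random lists, so gene length may account for its median of 0.26. The length in these trends is that of the gene in the genome, introns included, so neither trend tests the length of transcripts. A loss of short abundant transcripts, which dim genes near background cannot show, and a lower ribosomal expression in the sorted cell types, the biological explanation, cannot be told apart, because the tests turned on which genes count as bright: with brightness over all arrays, bright short genes had a median of 0.522 (-1.40 to 1.57, n = 11) and ribosomal protein genes lay -3.98 from them (-6.54 to -1.55). With brightness in whole embryo arrays, run first, the values were -3.65 (n = 39) and 0.185, and the other choice was made after that result was seen. The ranges given for bright short genes and for the distance from them came from resampling genes and leave out the spread between arrays.

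In whole gcm embryos bcd, tor and twe, known as maternal, rose by 1.62, 1.76 and 2.16 without the array labelled whole control 3. Against a response to gcm that sorted cells share, the biological explanation, the 3 genes had a median of 0.0807 in sorted gcm cells (-0.493 to 0.655), below each of their changes in whole embryos, and the difference between the effects was -1.52 (SE 0.39) for bcd and -2.07 (SE 0.55) for twe, though not called (adjusted p = 0.202 and 0.211). That range is the median with 2 median standard errors of a single gene on each side. These values argue against a rise in sorted cells as large as that in whole embryos. A smaller shared response is left open, since bcd and twe lay near background in sorted control cells (4.50 and 4.91). A rise in proportion to so low a level may not show. Younger or unfertilised embryos could raise maternal transcripts in general. A second maternal list had a median of 0.0534 (-0.149 to 0.339), too wide a range to decide, and -0.0266 with all arrays. Of its genes 16 of 25 were positive and 0 were called by limma (1622 probe sets with an unadjusted p under 0.05). The largest rises, picked after the values were seen, were those of smg, swa, plu, ea and wisp. They were 2.47, 1.67, 1.39, 1.23 and 0.98 (limma adjusted p from 0.0512 to 0.0929) and go with this explanation. Other members went the other way, with tsl at -0.51 and exu at -0.32 the lowest. The range for this list came from resampling its genes and leaves out the spread between arrays. The 2 explanations cannot be told apart with these arrays.

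For gcm in sorted cells 1 of 35 splits, the real one, gave as many calls, 17 against 3 at most in the others, and 108 against 79 without the array labelled whole control 3. The split with 79 calls set sorted control 2 and 3 and the twice-deposited sorted gcm array against the rest, so it parted replicate numbers 2 and 3 from 1 and 4. Chance is therefore excluded only where the replicate numbers are ignored. With the replicate number as a block, though, limma called 0 from all arrays (694 and 817 probe sets with an unadjusted p under 0.05), and 55 and 58 without that array. In whole embryos with all arrays again 1 of 35 splits gave as many, 8 against at most 3, which excludes chance only where the replicate numbers are ignored. Among the 8 splits that part all 4 pairs of the same number, too few for a share under 0.05, the highest other called 1, and with the number as a block limma called 0 (1454 and 1392 probe sets with an unadjusted p under 0.05). Chance cannot be excluded in the fit that leaves out the array labelled whole control 3, where 3 of 35 splits called 62 or more and the highest other called 462. That split set whole gcm 1 with the controls and called several times the real count, which points to a structure of the samples. The real split parts all 3 pairs of the same number and the 462 split parts 2. Among the 8 splits that part 3 pairs, too few for a share under 0.05, the highest other called 1. For sorting in controls 4 of 35 splits called as many, 3647 against 4930 when the array labelled whole control 3 was exchanged with a sorted control array, so chance cannot be excluded there. Without that array 1 of 35 did (6478 against 4132). It was left out for its likeness to sorted arrays, the contrast tested, so this count does not exclude chance by itself. Chance can be excluded in gcm embryos, where that array is in neither group, with 1 of 35 in both fits (5152 against 1442, and 6367 against 4013). For the interaction, splits within sorted and within whole embryo arrays turn an effect of gcm shared by both into a difference, so their counts (10 of 100 gave as many in both fits, 1 against 2, and 4 against 46 without that array) do not measure chance. With the shared effect, estimated from the real groups, removed before the splits, chance cannot be excluded with all arrays, where 12 of 100 gave as many, 1 against 2. Without that array 1 of 100 did, 4 against 3. So narrow a margin over drawn splits, in a test added after the result was seen, does not exclude chance. With the number as a block limma called 0 (1746 and 1761 probe sets with an unadjusted p under 0.05).

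The gcm level of whole gcm 1, 11.21, lay far from the other 3 whole gcm arrays. Control probe sets for 18S ribosomal RNA, in no comparison of genes, were higher in sorted than in whole embryo arrays by 7.11 (3' part), 6.54 (5' part) and 6.11 (middle), without the array labelled whole control 3 and after quantile normalisation, which puts the 3' and middle parts near the highest values of each sorted array, so that the sizes depend on that ceiling (on the deposited scale the 3' part had 12.95 and 6.21). By the test of the difference itself, the effect of gcm was called as different between sorted cells and whole embryos for MFS16, by 1.93 with all arrays. Without the array labelled whole control 3 the calls were Ect3 (3.02), Sardh (2.19), MFS16 (1.99) and CG3841 (1.50). Sardh and CG3841 lay under 5, near background, in every group but sorted gcm cells, so their sizes depend on the pseudocount. All these gene calls ended with the replicate number as a block, and chance was not excluded for them. For lists the median difference was 0.43 for Notch and -0.25 for cell cycle with all arrays, and 0.27 for Notch and 0.24 for ribosomal proteins without that array. These list calls ended with an estimated correlation (adjusted p = 0.628, 0.723, 0.727 and 0.842), and the other fit turned the sign for cell cycle (0.14, adjusted p = 0.704, without that array) and for ribosomal proteins (-0.54, adjusted p = 0.0593, with it).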

How the results depend on the processing

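The fits that combine the loss of the array labelled whole control 3 with another change, the count of both copies of the twice-deposited array and the quantile normalisation within sorted and within whole embryo arrays were chosen after the result was seen. The other settings, each array left out in turn among them, were fixed beforehand. With 28.1% to 35.8% of probe sets below an intensity of 16, signal over background limits small changes of dim genes. Quantile normalisation within sorted and within whole embryo arrays was not run for sorting, since it would normalise the groups compared separately. Of list results, 1782 kept their direction and side of the threshold, 49 were newly called, 59 lost their call and 0 reversed over the settings that kept all arrays or left out another array, and without the array labelled whole control 3 the counts were 1431, 76, 98 and 15. For named probe sets they were 13649, 223, 570 and 0, and 10397, 924, 75 and 1. The cause of the changes below was not tested, except where fewer arrays or fewer probe sets by construction could change a count.

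The values with all arrays were 17 calls for gcm in sorted cells, 8 for gcm in whole embryos, 3647 and 5152 for sorting in controls and in gcm embryos, 1 for the interaction, 0 shared by both gcm comparisons (limma, 776 and 1560 probe sets with an unadjusted p under 0.05), a correlation of 0.241 between the gcm effects, and 3, 7, 5, 6 and 2 called lists. A pseudocount of 1 gave 2 calls for gcm in whole embryos and a correlation of 0.188, and one of 64 gave 106 calls and 0 for the interaction (unadjusted p under 0.05 in 966). The values as deposited gave 3 calls for gcm in whole embryos, 0 for the interaction (921) and 4 lists for it. Median centring gave 68 calls for gcm in whole embryos and 0 for the interaction (798). Without the dimmest 40% there were 10 calls for gcm in sorted cells and 0 in whole embryos (1233), and without the intensity trend 3 in whole embryos. Array weights, lowest at 0.0837 for the array labelled whole control 3 against 0.448 to 2.80 for the others, gave 106 calls for gcm in sorted cells, 1144 in whole embryos with gcm itself called at 2.06, 6891 for sorting in controls, 59 for the interaction, 24 shared and a correlation of 0.119. Only the groups compared gave 39 calls in sorted cells with gcm called at 1.46, 0 in whole embryos (1092) and 0 for sorting in controls (4295). The replicate number as a block, with the twice-deposited array as number 2 or 3, gave 0 calls in sorted cells (694 and 817), 0 in whole embryos (1454 and 1392), 0 for the interaction (758 and 764) and, as number 3, 4 interaction lists. An estimated correlation left 0 lists in all 5 comparisons. Counting the twice-deposited array as 2 gave 49 calls in sorted cells, 69 in whole embryos, 3 for the interaction and 1 shared.

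Without the array labelled whole control 3 and with the values as deposited, there were 58 calls in sorted cells (gcm 1.92), 27 in whole embryos (gcm 2.23), 6080 for sorting in controls, 5 for the interaction, 10 shared, a correlation of 0.0780, 3 lists in whole embryos and 1 for the interaction, with the cell cycle list reversed in the interaction (0.39) and ogre reversed for sorting in controls at -0.052. With median centring the values were 54 (1.87), 100 (2.48), 7817, 2, 13 and 0.0780. With only the groups compared they were 38 (1.43), 13 (2.35), 5833, 6 shared and 0.106. With the block as number 2 they were 55 (1.46), 95 (2.39), 6098, 0 (1746), 10 and 0.101, with 5 lists in sorted cells and 3 in whole embryos, and as number 3 they were 58 (1.38), 31 (2.39), 6162, 0 (1761), 7 and 0.0929, with 3 lists in whole embryos. The ribosomal list reversed in the interaction (0.25 and 0.30).

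With each array left out in turn, from all arrays or after the array labelled whole control 3, calls ran from 8 to 183 for gcm in sorted cells, from 0 to 462 in whole embryos, from 1636 to 6560 and from 3805 to 6766 for sorting in controls and in gcm embryos, from 0 to 64 for the interaction and from 0 to 20 shared. The correlation ran from 0.0767 to 0.289, the gcm change from 1.29 to 1.60 in sorted cells and from 0.65 to 2.48 in whole embryos, and called lists from 2 to 5, 3 to 11, 3 to 7, 5 to 8 and 0 to 4. The arrays behind the extremes were, for sorted cells, sorted control 3 (8) and sorted control 4 (183 after the array labelled whole control 3), for whole embryos, whole gcm 1 (462), and for sorting in controls, whole control 4 (1636). Lists that reversed among these were Notch in sorted cells (from -0.19 to 0.26), EGFR and FGF signalling in whole embryos, by the direction of its test (from -0.52 to -0.023, with -0.074 where it reversed), and in the interaction cell cycle (from -0.48 to 0.23, with 0.12) and ribosomal proteins (from -0.88 to 0.46).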

Other observations

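The choice of values without the array labelled whole control 3 and of the genes named here came after the result was seen, while the lists, their tests and that fit, among those with each array left out in turn, were fixed beforehand. On sorting in controls, without the array labelled whole control 3, the heat shock and dissociation stress list had a median of 1.16 (adjusted p = 0.148) and was not called, with 9 of 14 genes that rose and 3 that fell over all probe sets, and 9 and 4 adjusted over the list alone. The phosphatase gene puc, a target of JNK signalling, rose by 3.24, the tumour necrosis factor gene egr by 2.14, kay, which encodes Fos, by 1.85, DnaJ-1 by 1.83, Hsp68 by 1.66, Hsf, the heat shock factor, by 1.63 and Jra, which encodes Jun, by 1.55. The glutathione transferase gene GstD1 fell by 2.47, the small heat shock gene Hsp26 by 2.02 and Irbp18 by 1.33. The median was 0.47 with the values as deposited, 0.89 with median centring and 0.71 with all arrays (adjusted p = 0.357). In gcm embryos it was 0.75 (adjusted p = 0.160). Of 8 genes of the apoptosis list (median 0.18, adjusted p = 0.318, and -0.20 with the values as deposited), grim, an activator of cell death, rose by 2.56, Dark, an adaptor of the apoptosome, by 1.48 and skl by 1.27, while the caspase gene Dcp-1 fell by 0.58.

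Lists of other cell types were not called on sorting in controls without the array labelled whole control 3, and their members moved in both directions, counted here over all probe sets. In the hemocyte list (median 0.33, adjusted p = 0.593) 8 of 27 genes rose and 5 fell, with the collagen genes Col4a1 at 2.34 and vkg at 2.22, and Nplp2 at -5.49. In the septate junction list (median -0.05, mean 0.42, adjusted p = 0.704) 7 of 17 rose and 5 fell, with the cell adhesion genes Nrg at 3.72 and Cont at 2.92, and bou at -2.51. In the neuroblast list (median 0.21, adjusted p = 0.463) 12 of 33 rose and 8 fell, with wor at 2.82, pros at 2.41 and mira at -2.25. In the mesoderm and muscle list (median 0.11, adjusted p = 0.488) 9 of 22 rose and 2 fell, with rst at 2.88 and sls, which encodes a titin-like protein, at 2.41. The endoderm, yolk and amnioserosa list (median -0.09, adjusted p = 0.849) had 3 of 24 genes that rose and 3 that fell, and the salivary gland list (median 0.57, adjusted p = 0.598) 3 of 8 and 1. In the germ cell and maternal list (median -0.27, adjusted p = 0.704) 4 of 17 rose and 3 fell, with tud at 3.31, vls at -2.15 and bcd at -1.37. In the segment polarity and pair rule list (median 0.40, adjusted p = 0.276) 8 of 18 rose and 2 fell, with nkd at 3.85 and drm at -2.78. With the values as deposited the medians turned to -0.11 for hemocyte, -0.33 for mesoderm and muscle, -0.10 for salivary gland, -0.40 for neuroblast and -0.20 for segment polarity, and with median centring that of the endoderm list turned to 0.075.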
